A study of Oikopleura dioica with 5 samples.

How the data were processed

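The series holds single-cell RNA-seq libraries of *Oikopleura dioica*, an appendicularian: a small planktonic tunicate that keeps a tail through life and lives in a secreted house. Per the labels' protocols, pooled maturing animals of mixed sexes were freed of their houses and digested with enzymes. The suspensions passed a 20 µm strainer, and 20000 cells per well were loaded on a droplet chip (10x Genomics GEM-X), which tags each RNA molecule with a cell barcode and a unique molecular identifier (UMI). Group and replicate number came from the labels: 2 early libraries (day 5), 2 mid libraries (day 6) and 1 late library (day 7). No label says that replicates came from separate pools of animals, so p-values measure only the spread between these libraries, which may be technical. The labels give no preparation batch, so stage and preparation day cannot be told apart.

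Per the file headers and the submitters' processing notes, the deposited matrices came from Cell Ranger 9.0.1. The aligned genome build and the annotation are not given in the sources used here. The deposited values are raw UMI counts per gene for every barcode, with no selection of cells, checked as whole numbers. All 5 libraries listed the same 17212 gene IDs. The files pair no ID with a name, and 0 of the IDs matched the RefSeq table of assembly OKI2018_I68_1.0. No gene, gene list or cluster could therefore be named. The gene lists and cell type markers fixed beforehand were not tested, and IDs are printed as the files give them.

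Total counts ran from 58183553 to 91217515 UMIs per library. Cells were barcodes above 10% of the 99th percentile of the UMI totals of the top 10000 barcodes, with at least 500 UMIs and 200 genes. This set thresholds of 5064, 6589, 3987, 3930 and 4126 UMIs for early replicates 1 and 2, mid replicates 1 and 2 and late. Scrublet marked at most 0.384% of the cells of a library as doublets. That is below the 0.5% at which its calls were to be used, so no cell was removed and doublets stay in the data. Removing the 5% of cells with the highest Scrublet scores served as an added alternative.

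For clusters, counts were scaled to 10000 per cell and log-transformed in scanpy 1.11.5. From 2000 variable genes, 30 principal components and 15 neighbours, Leiden clustering ran at resolution 1 with no integration of libraries. After the clusters were seen, they were merged into cluster groups by average linkage where 1 minus Pearson's r of their log2 CPM profiles stayed within 0.25. Barcodes too poor in UMIs to be cells were summed over 1 to 50 UMIs as planned, which lies below the mode of near-empty barcodes in early and mid, and over 51 to 150 UMIs as an addition. The latter spans those modes and is called free RNA.

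Raw counts were summed over the cells of a library and tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, its expression filter, Benjamini-Hochberg adjustment at 0.05). All 5 libraries entered 1 fit with a mean per stage and 2 residual degrees of freedom. The single late library was assumed to vary like the others. The same test ran on cells per cluster, on counts within clusters and on both ranges of near-empty barcodes. The planned test within clusters required 50 cells in each early and mid library, which no cluster had, so a minimum of 10 cells was used after the clusters were seen. DESeq2 1.42.0 was the alternative tool.

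Genes were classed by a fold of at least 4 in successive comparisons with both adjusted p-values under the threshold, a choice made after the comparisons were seen. IDs named for a comparison were fixed by rule before the data were examined: the 2 that rose and the 2 that fell with the largest fitted fold among called genes with a mean of at least 50 CPM in the higher stage and no overlap of libraries. Where a stage had 0 counts, folds are lower bounds set against 3 counts over the stage. Ratios and bounds of single genes use CPM without the TMM factors (0.87 and 0.862 in early, 1.41 and 1.40 in mid, 0.675 in late), while fitted log2 fold changes include them. Single-library shares carry exact binomial 95% intervals, which like the bounds cover counting error only. For a share of 0, the limit printed is 3 counts over the total and not the upper end of that interval.

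The test was tried on simulated counts in which 100 genes per fold size were changed, alternately up and down. For mid against early cells it recovered 80% of 2-fold and 100% of 4-fold changes among 15114 genes, with 8 false calls. For late against mid it recovered 55% and 96% among 15094 genes, and for late against early 46% and 95% among 15089. For barcodes with 1 to 50 UMIs, mid against early, it recovered 66% and 97% among 10005 genes. In the real data 12370 of 15464 genes were called for mid against early cells. The simulation does not cover changes this wide or their effect on scaling, so its rates may not hold there. Its changed genes were drawn only from those above a minimum expected count, and all genes had the same simulated spread. Recovery of genes with few counts is therefore not covered. Alternatives covered the tool, scaling, filters, cell threshold, thinning, clustering, range of near-empty barcodes, replicate block and leaving out each early or mid library.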

Results

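Single-cell transcriptomes of maturing *Oikopleura dioica* were compared at 3 stages: early (day 5, 2 libraries), mid (day 6, 2 libraries) and late (day 7, 1 library). The comparisons ask how the cells of the animal, male and female together, differ as it matures. The early libraries held 58183553 and 73314315 UMIs, the mid libraries 74456236 and 78332762, and the late library 91217515. Cells numbered 1943 and 1858 in early, 3296 and 3519 in mid and 2342 in late, 12958 in all. Median UMIs per cell were 14374 and 18413 in early, 9339 and 9123 in mid and 6592 in late. After thinning to 3000 UMIs, early cells showed a median of 895 and 890 genes, mid cells 1597 and 1567, and late cells 1314. Cells carried 65.4% and 64.8% of early UMIs, 57.1% and 57.4% of mid UMIs and 33.4% of late UMIs.

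**Figure D1:**
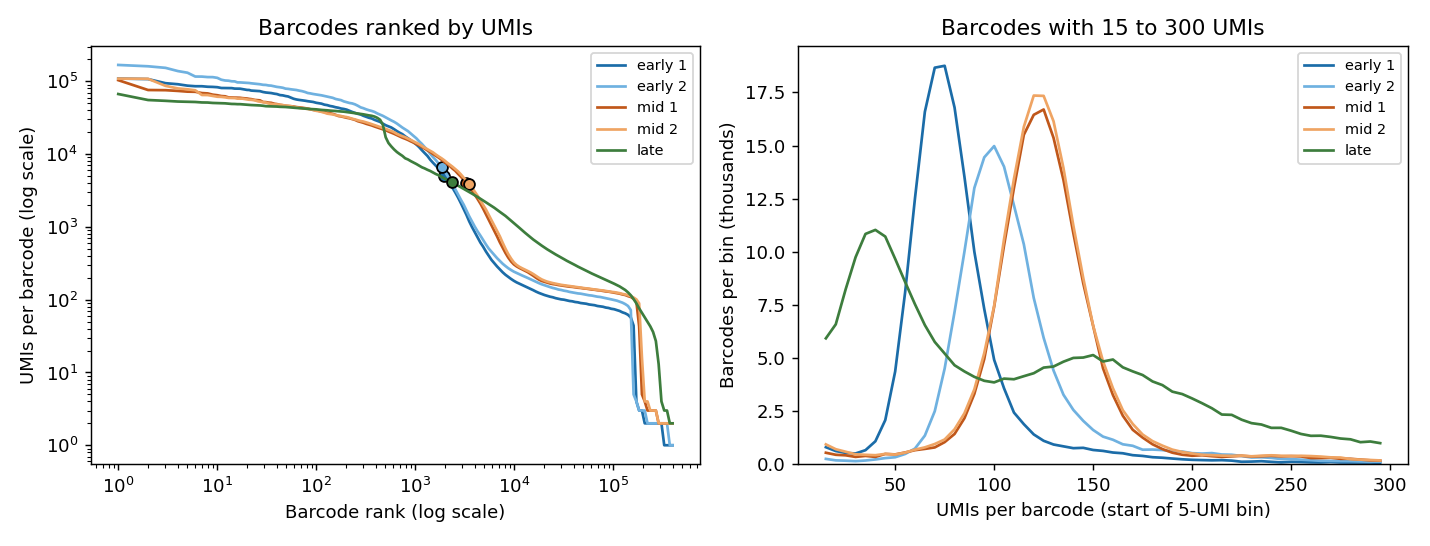
Left, UMIs per barcode against barcode rank for each of the 5 libraries, both axes on a log scale, with a point at each library's number of cells and UMI threshold. Right, barcodes per 5-UMI bin between 15 and 300 UMIs: each early and mid library has 1 mode, and the late library has modes in the bins starting at 40 and 145 UMIs. Modes were found on smoothed counts, while the lines are unsmoothed, and the highest late bin of the upper mode starts at 150 UMIs.

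Cells of the 3 stages fell into largely separate clusters. Of 37 clusters, 26 drew at least 95% of their weight from 1 stage when libraries were weighted equally, and these held 85.2% of cells. The clusters merged into 9 cluster groups. Cluster group 1, of 20 clusters and 8832 cells, held 54.9% ± 0.533 (SD, n = 2) of early cells and 98.97% ± 0.0891 (SD, n = 2) of mid cells. It held 0 of 2342 late cells, which allows a share of up to 0.128%. Cluster group 2, of 4 clusters, held 91.7% of late cells (exact binomial 95% interval 90.5 to 92.8%), 0 early cells and 4 mid cells (3 and 1). The limit of 0.128% takes the cluster groups as given, and these depend on where the linkage was cut. Late cluster 21 (259 cells) of cluster group 2 had r = 0.911 with mid cluster 12 of cluster group 1. With clusters 1, 13 and 17 of its own group, cluster 21 had r of 0.915, 0.737 and 0.810.

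Called cells of cluster groups 3 and 4 came from early and late, with at most 4 from a mid library. Cluster group 3, of 5 clusters, held 33.2% ± 0.640 (SD, n = 2) of early cells and 3.71% of late cells (87 cells, interval 2.99 to 4.56%). No cell of either mid library belonged to it, which allows shares of up to 0.0910% and 0.0853%. Cluster group 4, of 3 clusters, held 7.84% ± 0.124 (SD, n = 2) of early cells, 0 and 4 mid cells and 1.49% of late cells (interval 1.04 to 2.07%). For cluster group 4 this depended on the cell threshold: among barcodes with at least 500 UMIs, clusters led by it held 0.400% and 0.501% of mid and 0.255% of late barcodes. Cluster group 6, a single cluster, held 1.37% ± 0.192 (SD, n = 2) of early cells, 1 and 2 mid cells and 1.71% of late cells (interval 1.22 to 2.32%). With at least 500 UMIs, clusters led by it held 7.93% and 8.86% of early, 0.181% and 0.355% of mid and 3.88% of late barcodes. The early and late barcodes then lay in separate clusters, 1 with 396 and 491 early and 2 late barcodes and 1 with 819 late barcodes and 0 and 1 early.

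Smaller cluster groups had other distributions. Cluster group 5 held 1.94% ± 0.162 (SD, n = 2) of early cells, 0.308% ± 0.00650 (SD, n = 2) of mid cells and 1 late cell, but with at least 500 UMIs clusters led by it held 0.298% of late barcodes, near the 0.335% and 0.343% of mid. Cluster group 7 held 15 and 14 early cells, 7 and 2 mid cells and 0 late cells; with at least 500 UMIs, clusters led by it held 27 and 26 early, 28 and 17 mid and 14 late barcodes. Cluster group 8 consisted of 32 late cells, and cluster group 9 of 15 and 14 mid cells.

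**Figure D2:**
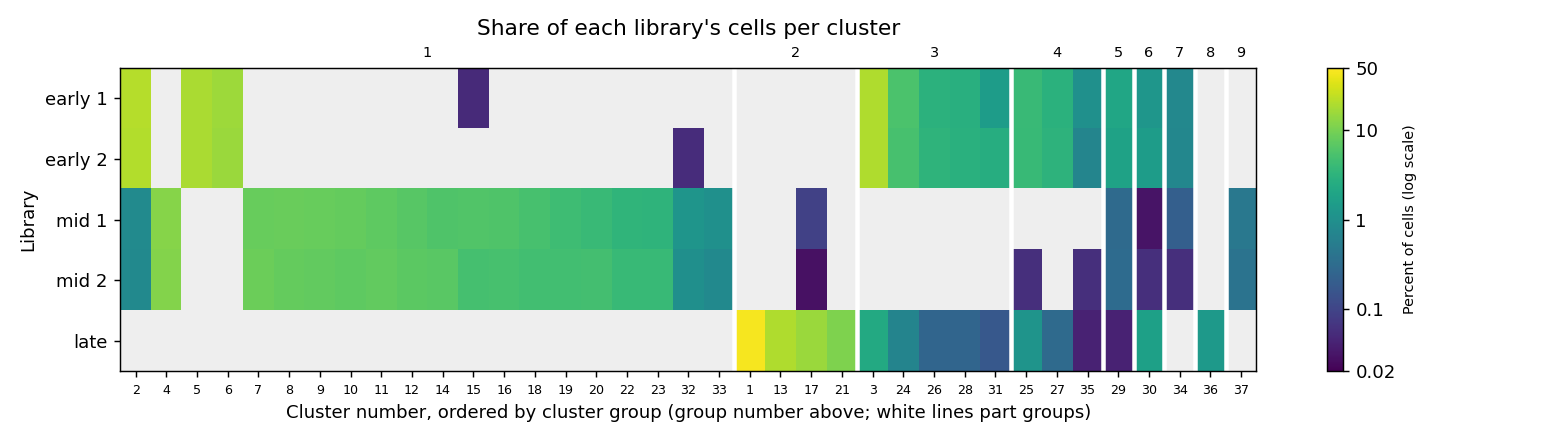
Share of each library's cells in each of the 37 clusters, as a percent on a log colour scale; grey marks 0 cells. Rows are libraries, columns are clusters ordered by cluster group, and the clusters of group 3 hold early and late cells and no mid cells.

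Cluster shares were tested between mid and early. Clusters 1, 13, 21 and 36 held no early or mid cell, so no difference could be called there. Of 37 clusters, 18 had a higher and 14 a lower share in mid (edgeR's quasi-likelihood test, adjusted p under the threshold). The clusters were built on genes that themselves differed between stages, so these counts describe how the transcriptomes part and not numbers of cell types. With all barcodes of at least 500 UMIs, 9 of 32 clusters had a higher and 13 a lower share in mid.

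Between early and mid, most genes changed, and falls outnumbered rises among changes of at least 4-fold. Of 15464 genes tested, 5788 rose and 6582 fell in mid (edgeR's quasi-likelihood test), and among those with a fold of at least 4 the counts were 1230 and 4715. GSOIDG00014677001 averaged 417 CPM in early (404 and 430) with 0 counts in mid, at least 12200-fold lower. GSOIDG00012670001 averaged 2090 CPM in early (2080 and 2110), with 3 counts in mid, an unscaled ratio of 61100 (counting interval 20900 to 296000). Both genes were among the 2 top genes of a cluster with 0 cells in each mid library. GSOIDG00014677001 had 10120 CPM in cluster 26 (cluster group 3) against 3.32 in the other cells. GSOIDG00012670001 had 70530 CPM in cluster 27 (cluster group 4) against 95.5. Their falls therefore do not show a change within cells. GSOIDG00007048001 rose from 0.263 and 0.232 CPM to 339 and 324 CPM (log2 fold change 9.68, SE 0.0963, adjusted p = 2.88e-06 by edgeR). GSOIDG00014496001 rose from 2 counts in early to 53.4 and 46.8 CPM (unscaled ratio 2140, counting interval 592 to 17700; fitted log2 fold change 10.22, which with 2 counts depends on the prior count).

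Scaling by library size alone gave 8074 rises and 5196 falls (2189 and 4097 at a fold of at least 4) and moved the median log2 fold change from -0.109 to 0.589, so the split over all genes depends on the scaling. Cells thinned to 500 UMIs each gave 4487 rises and 2484 falls among 10185 genes (1197 and 1914 at a fold of at least 4).

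Between mid and late, 7727 genes rose and 4769 fell, and with a fold of at least 4 the counts were 5585 and 1020 (edgeR's quasi-likelihood test, the 1 late library assumed to vary like the others). Sums over cells weigh each cell by its UMIs. The 461 late cells of cluster 13 (19.7% of late cells) had a median of 37170 UMIs, against 5935 in cluster 1 (45.6%). Late values here and below therefore give the cells of cluster 13 far more weight than their number. GSOIDG00006946001 had 0 counts in mid and 89.7 CPM in late, at least 2610-fold higher, after 178 and 158 CPM in early. GSOIDG00017980001 had 0 counts in mid and 105 CPM in late, at least 3050-fold higher (adjusted p = 0.0239 by edgeR), while its early libraries had 0 and 20 CPM. GSOIDG00003729001 fell from 123 CPM in both mid libraries to 1.90 CPM, an unscaled ratio of 64.7 (counting interval 50.0 to 85.3), with a fitted log2 fold change of -4.96. GSOIDG00002237001 fell to 1.51 CPM from mid libraries that themselves differed, at 29.7 and 103 CPM.

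Scaling by library size alone gave 5747 rises and 7066 falls (4446 and 3514 at a fold of at least 4), with the median log2 fold change at -0.33 in place of 0.73. The 4-fold falls numbered 2076 without early replicate 1 and 2065 without early replicate 2, and cells thinned to 500 UMIs gave 3687 rises and 2957 falls (2459 and 1069 at a fold of at least 4), with the median log2 fold change at 0.02.

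Between early and late, 5329 genes rose and 5286 fell, and with a fold of at least 4 the counts were 2882 and 1178 (edgeR's quasi-likelihood test, same assumption for late). GSOIDG00015162001 had 0 counts in early, 2.92 and 3.05 CPM in mid and 261 CPM in late, at least 7440-fold higher than in early. GSOIDG00011941001 had 0 counts in early, 2.77 and 3.78 CPM in mid and 220 CPM in late, at least 6270-fold higher than in early. GSOIDG00014760001 fell from 77.5 and 75.2 CPM to 0.427 CPM, an unscaled ratio of 179 (counting interval 104 to 336; fitted log2 fold change -7.12). GSOIDG00014759001 fell from 173 and 161 CPM to 1.18 CPM, an unscaled ratio of 141 (counting interval 102 to 201; fitted log2 fold change -6.78).

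Scaling by library size alone gave 4424 rises and 6590 falls (2457 and 1911 at a fold of at least 4), with the median log2 fold change at -0.45 in place of -0.09, and cells thinned to 500 UMIs gave 3124 rises and 2164 falls (1932 and 873). Without early replicate 1 there were 3505 rises and 6251 falls (2162 and 2171 at a fold of at least 4), and without early replicate 2 there were 3431 and 6209 (2138 and 2094).

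Over the 3 stages, the most common course among genes with 4-fold steps was a drop in mid. A class of 3873 genes was at least 4-fold lower in mid than in early and in late. Independent lists of the same sizes would share 1703 genes, and 20 simulated draws of unchanged stages sharing the mid libraries gave 0, a value nearly fixed by asking for 4-fold steps of unchanged genes. Part of the excess may come from the shared mid libraries. These genes took 17.6% and 17.3% of UMIs in early cells, 1.96% and 2.08% in mid cells and 12% in late cells. In early cells alone they took 42.3% of UMIs in cluster group 3, 24.2% in cluster group 6, 20.0% in cluster group 4 and 16.6% in cluster group 7, against 8.91% in cluster group 5 and 6.81% in cluster group 1. In the mid cells of cluster group 1, where the class is low by its definition, they took 1.99%. In the 21 mid cells of cluster group 5 they took 6.62%, near the early value of that group, and in the 29 of cluster group 9 3.44%. In late cells they took 51.8% in cluster group 3, 24.9% in cluster group 6, 20.9% in cluster group 4, 19.4% in cluster group 8 and 10.9% in cluster group 2. With cells thinned to 500 UMIs, the class held 1378 genes.

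A second class rose at each step. It held 512 genes, where independent lists would share 444, and took 0.1% and 0.099% of UMIs in early cells, 2.10% and 2.13% in mid cells and 16.4% in late cells. Another 111 genes were at least 4-fold higher in mid than in early and late (81 for independent lists), and 4 genes fell at both steps (311 for independent lists). A set of 906 genes was at least 4-fold higher in late than in both other stages with no such step between early and mid. It took 1.44% and 1.38% of UMIs in early cells, 2.67% and 2.57% in mid cells and 14% in late cells. The opposite set, at least 4-fold lower in late than in both other stages, held 328 genes and took 1.71% and 1.80% of UMIs in early cells, 2.28% and 2.48% in mid cells and 0.188% in late cells.

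**Figure D3:**
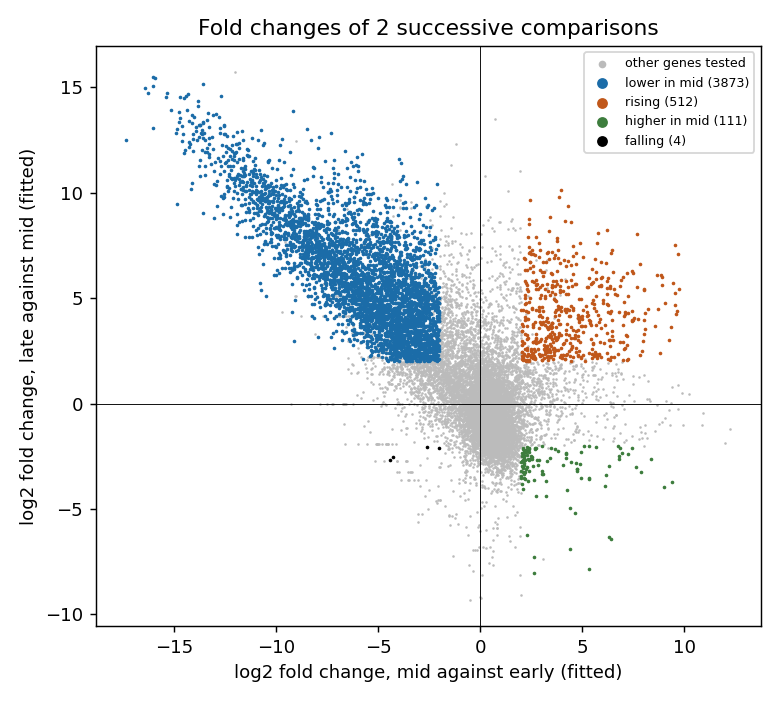
Fitted log2 fold change of late against mid plotted against that of mid against early, 1 point per gene tested; colours mark the classes with a fold of at least 4 in both comparisons. The upper left holds the 3873 genes lower in mid, the upper right 512 rising genes.

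Genes were also compared within the clusters that held at least 10 cells of each early and mid library. In cluster 2, part of cluster group 1, 1018 genes rose and 1374 fell in mid among 8400 tested. In cluster 29, which is cluster group 5, 219 rose and 298 fell among 2560 (edgeR's quasi-likelihood test in both). Of the 1971 genes called both within cluster 2 and in all cells, 1494 moved the same way, and in cluster 29 the count was 308 of 424. Cells join a cluster by their expression, and the mid libraries had only 28 and 29 cells (283175 and 260902 UMIs) in cluster 2 and 10 and 11 in cluster 29, so these counts cannot be set against those of all cells. Between all cells of cluster group 1, 4455 genes rose and 4240 fell in mid among 12029 tested (1160 and 1447 at a fold of at least 4), with free RNA not removed. Without early replicate 1 or 2, the calls over both clusters dropped from 2909 to 1703 and 1684.

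Barcodes too poor in UMIs to be cells were tested in the same way. The planned range of 1 to 50 UMIs lies below the mode of near-empty barcodes in each early and mid library (bins starting at 75 to 125 UMIs), so it does not stand for the RNA of empty droplets. In it, 2684 genes rose and 3276 fell in mid among 10661 tested (edgeR's quasi-likelihood test). Of 5640 genes called both there and in cells, 99.1% moved the same way: 2599 rose in both and 2990 fell in both, where independent lists would share 1324 and 1119. In barcodes with 51 to 150 UMIs, which span the early and mid modes, 92% of 10021 genes called in both moved the same way: 4288 rose and 4929 fell in both, against 2114 and 2583 for independent lists. Both sets of sums come from the same libraries, so they are not separate evidence. The genes lower in mid took 24.4% and 25.1% of UMIs in early barcodes with 51 to 150 UMIs, 3.60% and 3.69% in mid and 13.4% in late. The split depended on the UMI range: barcodes with 1 to 20 UMIs gave 4275 rises and 2548 falls, with the median log2 fold change at 0.43 in place of -0.02. DESeq2 called 3676 genes in barcodes with 1 to 50 UMIs, and edgeR called 11638 in those with 51 to 150 UMIs.

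**Figure D4:**
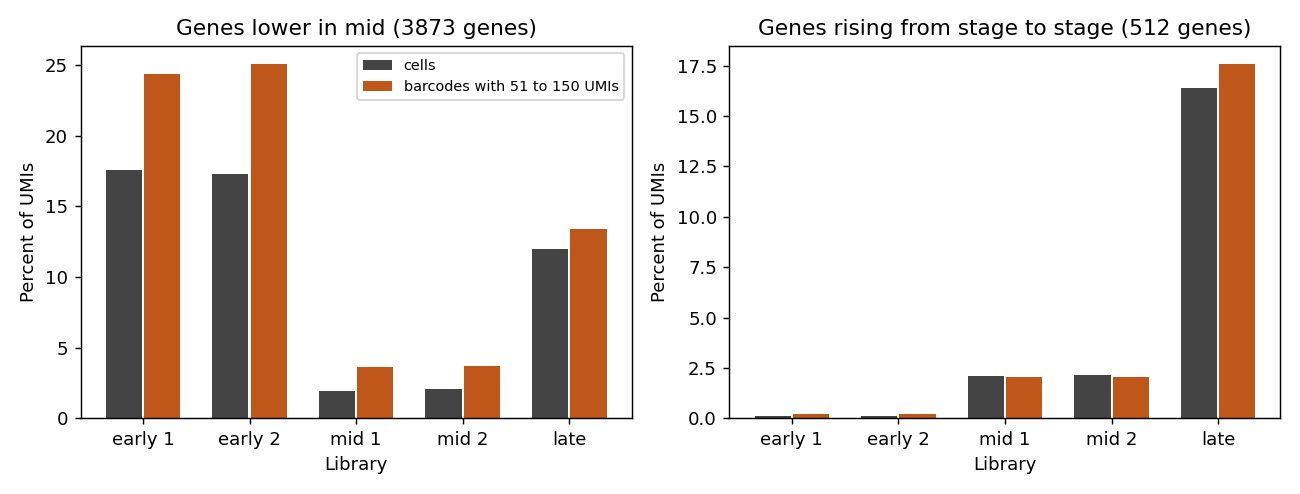
Percent of all UMIs taken by the 3873 genes lower in mid (left) and the 512 rising genes (right) in each library, in cells and in barcodes with 51 to 150 UMIs. Bars are single libraries without error bars; the mid libraries are at 1.96% and 2.08% in cells for the genes lower in mid.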

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

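Tests in this part were chosen after the patterns were seen, except the median fold change and the excess over free RNA within cluster group 1; the genes counted in the latter were changed after a first value, and the subtraction of free RNA was added after both, with its bound set before its value but its form changed from a median to a percent of genes afterwards.

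The late library held 18829 barcodes between 500 UMIs and its cell threshold, against 3062 to 4657 in the others, and no comparison of called cells uses them. The threshold rule takes 10% of the UMIs near rank 100, which were 41266 in late. Late UMIs per barcode then fell from 29637 at rank 442 to 14216 at rank 537. The threshold was thus set by barcodes far richer in UMIs than most late cells (median 6592). The summed profile of the 18829 barcodes below the threshold correlated across 7696 genes with late free RNA (r = 0.96) and with late cells (r = 0.931). When all barcodes with at least 500 UMIs were clustered, 67.0% of late barcodes joined clusters led by cluster group 2, 6.63% those led by cluster group 3 and 20.2% clusters with under 20 called cells. In that clustering the mid libraries had 6 and 2 barcodes in clusters led by cluster group 3, and the early libraries 1546 and 1819. Of the 1403 late barcodes there, 1249 lay in a cluster with 1 barcode of each early library.

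The late library also had 2 modes of near-empty barcodes, in the bins starting at 40 and 145 UMIs of the smoothed histogram, where every other library had 1. Without smoothing, the upper mode was highest in the bin starting at 150 UMIs (5139 barcodes, against 5022 in the bin starting at 145). The low mode, from 20 to under 80 UMIs, held 100450 barcodes. One suspension caught in droplets of 2 sizes stays open: r between the 2 UMI ranges lay 0.086 under that of random splits of either range. Single-mode libraries dropped too, by 0.072 in early replicate 1, 0.027 in early replicate 2 and 0.031 and 0.025 in mid. The bound of 0.02 set for this test was thus wrong. Early replicate 2 and mid had fewer UMIs for this than the other libraries. In late, 1679 of 7635 genes were over 2-fold higher in the high range and 0 in the low range, a count not made in other libraries. Barcodes of 2 wells or suspensions read as 1 library may account for the 2 modes, since the late library had 1.37 times the barcodes over 30 UMIs of the highest other library. However, the single-mode libraries already differ by up to 1.24 times among themselves. No biological explanation was tested.

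The second pattern weighed is the class of 3873 genes lower in mid than in early and late. A cell threshold that left cells out of mid was tested over every barcode. There the mid share of these genes, 0.128 of the early share, missed the bound of 0.1. A second test was added, with its bound set after class sizes were seen. In it 91.5% of these genes stayed in the class (97.7% with at least 500 UMIs), which argues against the threshold as the main cause. Sums over every barcode include the called cells that defined the class (57.1% and 57.4% of mid UMIs). Staying in the class is thus partly built in. For 463 genes over 20 CPM in both early libraries and under 1 CPM in both mid libraries the share ratio was 0.0048. Cells that burst in mid are argued against as the main cause for those 463 genes, at 0.00523 of the early share in barcodes with 51 to 150 UMIs, but stay open for the whole class, at 0.147 with 68.9% of genes still in it. In mid the 463 genes took 0.0642% and 0.0563% of UMIs in that range, against 0.00831% and 0.00842% in cells, for which they were picked as low. In early the shares were 11.3% and 11.8% against 7.19% and 7.14%. Some burst cells in mid are thus not excluded. Fewer cells of other cluster groups, with no change within cluster group 1, is argued against only for the UMIs of the class: their share within group 1, less the highest free RNA level, was at least 3.04 times as high in early as in mid (2.66 without the 4 genes that made up 50% of the excess, 2.95 for the median cell, which a minority of doublets would not move). The class was picked from these libraries for low mid values, and mid cells were 98.97% cluster group 1. A lower mid share within the group is thus partly built in, and the ratio does not stand for the group's other genes. Among all genes tested in cluster group 1, 4455 rose and 4240 fell in mid. Gene by gene this explanation stays open. The median log2 fold change of -2.92 over 1701 genes (bootstrap interval -3.02 to -2.78) passed the bound of -2, but that bound left out free RNA. These were the genes of the class that passed the expression filter within the group. Picked as low in mid, they could pass it through their early counts, so a low median is partly built in. The interval treats genes as independent. After subtraction of the highest free RNA level, 19.2% of 1548 genes were over 2-fold lower in mid (42.1% at the median level). This lies on the side the explanation predicts. However, at the highest level 47.8% of the genes had nothing left in early and were counted as not lower, so the low percent cannot favour it. Of the 1548 genes 47.2% exceeded 2 times the median free RNA level (24.7% at the highest level), where a first form limited to genes seen in those cells gave 72.0%. Maturation itself, the preparation day and loss of cells before loading remain untested.

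The third pattern is GSOIDG00012841001, singled out after its values were seen: 25183 and 47042 CPM in the early cells and 7048 and 20052 CPM in the mid cells, higher in replicate 2 each time. A different mix of clusters is argued against by the ratio within clusters of at least 20 cells per replicate, whose lowest value was 1.75. A library-wide cause may act on all droplets alike: the ratio in free RNA was 2.97 in mid and 1.81 in early, inside the ranges within clusters of 2.26 to 3.22 and 1.75 to 1.93, while barcodes with 1 to 50 UMIs gave 3.36 in mid, slightly above that range. Free RNA of a suspension would share a ratio found in all its clusters whatever the cause, so this test cannot favour that one. Of 1460 genes with at least 50 CPM in these 4 libraries, 4 differed over 1.5-fold between early replicates, 15 between mid replicates and 1 between both. No biological explanation was tested.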

How the results depend on the processing

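Alternatives added after seeing the data were library size scaling, removal of the highest Scrublet scores, clustering on uncalled genes, barcodes with 51 to 150 UMIs, and every alternative for the within-cluster and gene class results. Thinning to 500 UMIs gave 6971 genes for mid against early, 6644 for late against mid, 5288 for late against early and 1378 genes lower in mid; fewer genes were tested (10185 against 15464). Clustering on uncalled genes gave 3 differing clusters of 8; these genes were picked for not differing and that clustering separated the mid replicates (chi-square 3232), so it does not test the shares. Near-empty barcodes gave 11638 calls at 51 to 150 UMIs and 3676 with DESeq2 at 1 to 50 UMIs; the cause was not tested. Leaving out 1 library gave 10680 to 11992, 12083 to 12372 and 9640 to 11017 genes in the 3 comparisons, 32 to 33 clusters, 1684 to 2207 calls within clusters (fewer genes tested without an early library), 4034 to 5650 in barcodes with 1 to 50 UMIs, 3415 to 3784 genes lower in mid and 393 to 508 rising. Without an early library, rises were 35.6% to 35.9% of late against early calls, against 50.2%. Other total counts stayed within 1.5 times, but their parts moved more: 4-fold falls in late against mid went from 1020 to 2076 and 2065 without early replicate 1 and 2 and to 3514 by library size, those in late against early from 1178 to 2171, 2094 and 1911, and 4-fold rises in mid against early from 1230 to 2189 by library size. Clusters higher in mid went from 18 to 9 at 500 UMIs, and rises in near-empty barcodes from 2684 to 4275 at 1 to 20 UMIs, to 1400 with DESeq2 and to 1607 and 1618 without early replicate 1 and 2. Within clusters, rises went from 1237 to 618 without either early library and to 802 and 808 without mid replicate 1 and 2, and 4-fold falls from 384 to 225 with DESeq2.

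Replicate numbers were not taken to pair the samples: no label says so, and deviations of same-numbered libraries correlated across 6200 genes at r = 0.079, although the 11 genes that differed by over 0.25 (log2) between replicates of both stages all moved the same way. With a replicate block, 11982 genes, 32 clusters, 2711 calls within clusters and 5400 genes in barcodes with 1 to 50 UMIs were called. No difference in cluster make-up between replicates was detected in called cells (chi-square p = 0.775 early, 0.525 mid), but early replicates differed at 500 UMIs (p = 2.09e-06) and on uncalled genes (p = 2.4e-05). Gene sums of replicates differed beyond counting noise when averaged over genes (chi-square per gene 39.2 between early and 57.7 between mid libraries). Abundant genes such as GSOIDG00012841001 weigh heavily in this mean, and it leaves out the sampling of cells. It therefore does not show that genes in general differed.

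Not run were the gene lists, whose genes no table named, and the within-cluster test at 50 cells; keeping Scrublet calls equals the reported setting. The late stage has 1 library and no replicate check.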

Other observations

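Both tests in this part were chosen after the patterns were seen.

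Mid clusters of cluster group 1 differed in likeness to the other stages. Over 17 mid clusters, mean r with the 3 early clusters of the group ran from 0.793 to 0.922, and mean r with the 4 clusters of cluster group 2, nearly all late cells, from 0.452 to 0.717. Mid cluster 12 was closest to the late side, at r = 0.911 with late cluster 21. A hypothesis is that mid clusters lie along 1 axis from early to late: Spearman's rho between the likenesses was -0.65, which is consistent with it. Clusters are not independent samples, and likeness to late also ran with median genes per cell (rho 0.52), so depth may contribute.

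Genes with consecutive ID numbers changed alike. Across 4660 such pairs, Pearson's r of the mid against early log2 fold changes was 0.51, where the highest of 1000 shuffled orders gave 0.048. For late against mid it was 0.512 and for late against early 0.327. At a distance of 2 IDs r was 0.316 and at 5 IDs -0.048 for mid against early. Chance order is thus argued against. If IDs follow position, which the files do not state, neighbouring genes or near-identical copies sharing reads may change together, and neither was tested. Genes are not independent replicates.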
